A study of Mus musculus with 20 samples.

How the data were processed

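Gene expression was measured by RNA sequencing in 20 libraries of mouse splenic T effector cells. Per the labels' protocols, CD4+CD25- cells were sorted from mice carrying a floxed Pcbp2 gene with the CD4-Cre driver (CKO) and from control littermates (CTL), and were frozen either at once (0 h) or after 6 h with beads that bind CD3 and CD28. Stranded, poly(A)-selected libraries were made from 100 ng of total RNA with integrity numbers of 5.0 to 8.7 (median 7.4) and were sequenced as paired ends on an Illumina HiSeq, again per the labels. The groups hold 6 CTL and 6 CKO libraries at 0 h, and 5 CTL and 3 CKO libraries at 6 h. Each title carries a number such as 4.29 or 5.13, used here as the name of a library within its group; the labels do not say whether it marks an animal, a litter or a day.

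The authors deposited a single table of whole-number counts per Ensembl gene, with 1 column per library and no normalization. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.2b, featureCounts, Subread 1.5.2 and the build GRCm38, without roles or settings. The annotation release and the strand setting of the counting are not given in the sources used here, so values of genes that overlap another gene on either strand are uncertain. Of 49315 gene IDs, 49056 were matched to GENCODE M21 by their identifier and took their symbol and GRCm38 coordinates from it, and 259 were not matched. The table held 0 columns of other samples. Counts per library summed to between 26.4 M and 85.6 M, and levels are given as counts relative to the TMM-scaled library size (CPM). The precision of a group value rests on the spread between libraries, and no interval for counting error is given. No library was a copy of another: over 43 pairs of libraries within groups, the chi-square per degree of freedom of their counts lay between 21.5 and 303, where sampling noise alone gives about 1.

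Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 28082; TMM factors scaled the libraries, and a quasi-likelihood model with robust estimation (glmQLFit, glmQLFTest) held the 4 groups and the sex given in the labels. All 20 libraries entered this fit and shared its estimate of the spread, since the smallest group had 3 libraries. The contrasts were CKO against CTL at 0 h, CKO against CTL at 6 h, 6 h against 0 h in CTL, 6 h against 0 h in CKO, and the difference between both responses (the interaction). A gene is called where its two-sided p, adjusted by Benjamini and Hochberg over the 28082 genes, lies under 0.05. Every adjusted p given for a gene comes from this test unless another tool is named, and values after ± are standard errors for log2 fold changes and standard deviations (SD) for CPM. Pcbp2 itself was also compared by an exact two-sided permutation test of log2 CPM.

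There were 38 gene lists tested with camera (limma 3.58.1) on voom values with the same design and a preset inter-gene correlation of 0.01, adjusted over the lists of each comparison; camera with an estimated correlation and fry were run beside it. For each list the called members are counted, once with p adjusted over all genes and once adjusted over the list alone. The overlap of genotype calls between 0 h and 6 h was tested with a one-sided Fisher exact test for each direction. These designs, the lists, the first set of alternatives and the rule for naming genes were written before the data were examined. By that rule the text names Pcbp2 and its relatives; the 8 called genes with the largest rise and the 8 with the largest fall at a mean log2 CPM of at least 2, leaving out sex-linked genes, predicted or clone-named models and antigen receptor segments; and, from each list, up to 4 called members with the smallest adjusted p, or up to 2 of the most abundant members by value where none was called. Genes named outside the rule are said to have been chosen after their values were seen.

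Alternatives set beforehand were RLE factors, no filter beyond a single count, DESeq2 1.42.0, no sex term, the number as a block, voom with number and genotype together as a random block, only the groups compared, only libraries labelled male, 1 surrogate variable (sva 3.50.0), a test against a fold of 1.5, and leaving out each library in turn. Further alternatives were added after seeing the data: a mean CPM of at least 1 as the filter, the level of the Y-linked gene Ddx3y or a sex read from Xist in place of the sex label, and leaving out the 6 h CTL library 4.24 or a pair of 0 h CKO libraries whose Xist levels disagreed with their label. Whether the numbers pair libraries was checked on the residuals from the group means, before any calls were compared. Same-numbered CTL and CKO libraries at 0 h correlated at 0.25 to 0.70 in the 5 pairs. Same-numbered CTL libraries at 0 h and 6 h did so at 0.26 to 0.52 in the 5 pairs, so the numbers pair these groups. Between groups the median was 0.35 for the same number and −0.07 for other numbers. Correlations between other numbers ran from −0.56 to 0.62 and so overlap those of the same number. The paired fit with the number as a block called 290 genes for genotype at 0 h, 101 of them also called in the main fit. This fit kept the sex label beside the number. Within a number the label differed only for the 0 h CKO libraries whose Xist levels disagreed with it. Its sex term rests on them, so its genotype values are not those of pairing alone. The main fit was set beforehand without the block and gives the values below unless the block is named. In CKO the 0 h and 6 h pairs correlated at 0.10 to 0.50, so the lowest was not over the limit of 0.1 set for every pair, and the genotypes at 6 h share a single number.

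The scripts were tested on simulated counts with 200 changed genes, drawn from those with a mean CPM of at least 1. Apart from these changes, each gene had a common mean and a spread set by the trend with abundance. Sex effects, pairing by number and background reads were not simulated, so shares in the real data may differ. For CKO against CTL at 0 h (27528 genes), edgeR recovered 35.8%, 71.6% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold; at 6 h (27538 genes) it recovered 22.4%, 61.2% and 95.5%. In the same order the recovered shares were 38.8%, 71.6% and 97% for 6 h against 0 h in CTL (27517 genes), 20.9%, 71.6% and 97% in CKO (27513 genes), and 7.46%, 29.9% and 78.8% for the interaction (27516 genes). Among the simulated calls, 6 were false in edgeR at each time of the genotype comparison, and DESeq2 made 31 false calls among 173 at 0 h and 29 among 154 at 6 h. Figures were drawn in Python 3.11.15 from the same tables.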

Results

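The study asked which genes differ in expression between splenic T effector cells with and without the RNA-binding protein Pcbp2, at rest and after activation. Sorted CD4+CD25- cells, more than 99% pure per the labels, came from CTL and CKO littermates, with deletion driven by Cre recombinase under the Cd4 promoter, which acts in developing T cells. RNA was sequenced from 6 CTL and 6 CKO libraries of unstimulated cells (0 h) and from 5 CTL and 3 CKO libraries of cells kept for 6 h with beads that bind CD3 and CD28, the antigen receptor complex and its main costimulatory receptor. Total counts per library ran from 71.0 M to 79.3 M in CTL and from 68.8 M to 85.6 M in CKO at 0 h, and from 65.3 M to 76.8 M in CKO at 6 h. In CTL at 6 h, 4 libraries held 62.4 M to 69.4 M counts and library 4.24 held 26.4 M. The labels name littermates but do not tie single libraries to animals, so the p-values below measure the spread between these libraries. All 6 CKO libraries at 0 h were labelled male, but the libraries labelled CKO 4.24 and CKO 5.6 had 1130 and 1317 CPM of the female-specific transcript Xist and 0.277 and 0.113 CPM of the Y-linked gene Ddx3y.

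Pcbp2 (ENSMUSG00000056851, GRCm38 chromosome 15, 102470539 to 102500061) was nearly lost in every CKO library. At 0 h its level was 17.0 ± 3.39 CPM (SD, n = 6) in CKO and 333 ± 46.9 CPM (SD, n = 6) in CTL, so that 5.09% of the CTL level was left. At 6 h it was 8.72 ± 2.24 CPM (SD, n = 3) in CKO and 322 ± 34.5 CPM (SD, n = 5) in CTL, leaving 2.70%. The exact permutation test gave p = 0.00216 at 0 h over 924 assignments and p = 0.0179 at 6 h over 56 assignments, at each time the smallest value these groups allow. Paired by number as a block, the 5 numbers present in both genotypes at 0 h left 4.89%, and the exact sign-flip test reached p = 0.0625, the smallest value that 32 sign flips allow. Counts cover the whole gene, so reads from exons outside the deleted part are included. None of the measured relatives, which bind similar cytosine-rich RNA, was called. Log2 fold changes at 0 h and 6 h were 0.05 ± 0.14 and −0.04 ± 0.17 for Pcbp1, 0.10 ± 0.11 and 0.14 ± 0.13 for Pcbp3, 0.02 ± 0.13 and 0.26 ± 0.15 for Pcbp4, and −0.02 ± 0.11 and 0.03 ± 0.13 for Hnrnpk. With Pcbp2 among its 5 members the family list was called lower at 0 h by camera (adjusted p = 0.00836; adjusted p = 0.339 with an estimated correlation), while its median log2 fold was 0.03. With the number as a block the list was no longer called (adjusted p = 0.182).

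**Figure D1:**
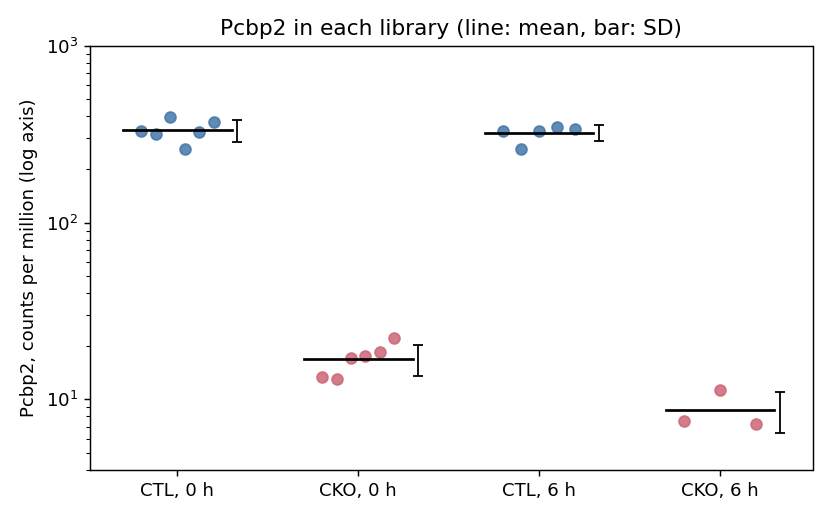
Pcbp2 level in every library, in CPM on a log axis, by genotype and time; points are libraries and bars the group mean with its SD. The 9 CKO libraries lie between 7.27 and 22.1 CPM, below the 11 CTL libraries at 261 to 396 CPM.

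In unstimulated cells, loss of Pcbp2 went with a limited set of changes in named genes. Syn3, a synapsin, was 16-fold higher in CKO by the fit with its sex term. Its group means were 15 ± 3.05 CPM (SD, n = 6) in CKO and 1.13 ± 0.252 CPM (SD, n = 6) in CTL. Myo6, an unconventional myosin that moves toward the minus end of actin filaments, rose 4.55-fold, and Ptgir, the prostacyclin receptor, rose 3.08-fold. Prss12, a secreted serine protease, was 5.01-fold lower. Each of these was higher or lower in 6 of 6 CKO libraries than the CTL mean. Log2 fold changes were 4.0 ± 0.23 for Syn3 (adjusted p = 1.39e-09), 2.19 ± 0.18 for Myo6 (1.15e-06), 1.62 ± 0.17 for Ptgir (2.85e-05) and −2.33 ± 0.25 for Prss12 (2.85e-05).

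Other called rises at 0 h were Lmna, which encodes the A-type lamins of the nuclear envelope (1.44 ± 0.18), the laminin chain gene Lamc1 (1.41 ± 0.22), Igsf23 (1.29 ± 0.17), the chemokine receptor gene Ccr6 (1.46 ± 0.31, adjusted p = 0.0416), and Epb41l5 (1.38 ± 0.30, adjusted p = 0.0453). The remaining falls among the named genes were Adam1a (−1.29 ± 0.20), the phospholipid-transporting ATPase gene Atp8b4 (−1.24 ± 0.21), Btbd2 (−1.21 ± 0.14), the RNA-binding protein gene Raver2 (−1.16 ± 0.18), the γ-glutamyltransferase gene Ggt5 (−1.15 ± 0.14) and Fbxo24 (−1.12 ± 0.21). In all, 119 of 28082 genes were called, 65 higher and 54 lower in CKO, and 73 of them changed at least 2-fold. With the Ddx3y level or a sex read from Xist in place of the sex label, both chosen after seeing the data, 224 and 223 were called. All of the calls on Syn3, Myo6, Ptgir, Lmna, Igsf23, Prss12, Btbd2 and Ggt5 held in each of the 20 fits that left out a library. Calls near the threshold did not hold throughout. Ccr6 was no longer called in 14 of those fits (adjusted p up to 0.174, without CTL_0h 4.29), Epb41l5 in 16 (up to 0.0982) and Fbxo24 in 5 (up to 0.0873).

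Among the gene lists at 0 h, those of regulatory, Th17 and T follicular helper cells and of mitosis lay higher in CKO. Camera called 16 of the 38 lists (12 higher, 4 lower), and 0 with an estimated correlation. Fry called 1 list, a lower one that was among the 16. Without the sex term 10 of the 16 calls stood. With the Ddx3y level among genes with a mean CPM of at least 1, a setting chosen after seeing the data, 8 stood. On the regulatory T cell list 12 of 13 members had a positive fold (median log2 0.53, camera adjusted p = 3.13e-07; adjusted p = 0.356 with an estimated correlation). Gpr83, a receptor typical of regulatory T cells, was called (1.18 ± 0.23, adjusted p = 0.0227), and 6 members were when adjusted over the list alone. On the Th17 list, for helper cells that make interleukin 17, 8 of 9 members were positive (median 0.98, adjusted p = 5.27e-05; 0.356 with an estimated correlation). Ccr6 was called, and 5 members were when adjusted over the list alone. Members Il17a, Il17f, Il22 and Il23r had mean levels under 1 CPM in both genotypes at 0 h. The T follicular helper list was positive in 11 of 11 members (median 0.45, adjusted p = 0.000339; 0.491 with an estimated correlation), with 0 called by edgeR (5 at an unadjusted p under 0.05, 1 called by DESeq2) and 1 adjusted over the list alone. All 24 mitosis genes were positive (median 0.46, adjusted p = 1.31e-08; 0.437 with an estimated correlation), though edgeR called 0 over all genes or adjusted over the list alone (4 at an unadjusted p under 0.05) and DESeq2 called 0. Mki67 stood at 0.39 ± 0.38. Of 18 p53 target genes 15 were positive (adjusted p = 0.000242; 0.339 with an estimated correlation). Cdkn1a, a cell cycle inhibitor, was called at 1.23 ± 0.26 (adjusted p = 0.044), against 3 adjusted over the list alone. That call ended in 15 of the 20 fits without a library (adjusted p up to 0.178, without CTL_0h 4.29), and the one on Gpr83 in 2 (up to 0.0767, without CTL_0h 9.20).

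Markers of other cell types lay higher with these lists at 0 h. The myeloid list was positive in 14 of 14 members (median 0.70, adjusted p = 3.13e-07), the B cell list in 17 of 17 (median 0.75, adjusted p = 0.000129), the dendritic cell list in 8 of 8 (adjusted p = 0.0143) and the stromal and endothelial list in 7 of 7 (adjusted p = 0.0117). Their adjusted p with an estimated correlation was 0.339, 0.437, 0.491 and 0.388. Over these 4 lists edgeR called 0 members, against 6, 0, 0 and 2 at an unadjusted p under 0.05. DESeq2 called 1, on the stromal list, where 1 was also called when adjusted over the list alone. Lower lists were ribosome biogenesis, with 1 of 25 members positive (median −0.14, adjusted p = 0.00372), Th1 (median −0.26, adjusted p = 0.0131) and naive and quiescence, with 8 of 24 positive (median −0.08, adjusted p = 0.0382). With an estimated correlation these were 0.772, 0.387 and 0.772. On these 3 lists edgeR called 0 members, against 1, 2 and 1 at an unadjusted p under 0.05, 0, 0 and 1 by DESeq2, and 0, 0 and 1 adjusted over the list alone. With the number as a block the Th1 and naive lists were no longer called (adjusted p = 0.135 and 0.0896). By edgeR none of the following genes was called: Cd4 stood at 0.13 ± 0.18, Ptprc at −0.05 ± 0.16 and Tcf7 at −0.14 ± 0.16, and the transcription factor Runx1 at 0.36 ± 0.13 (adjusted p = 0.439). DESeq2 called 421 genes, including 118 of the 119. The fit with the number as a block beside the sex label called 290, of which 69.3% were higher in CKO against 54.6% without the block. Its sex term rests on CKO_0h 4.24 and CKO_0h 5.6, whose labels disagree with Xist. Lower calls outnumbered higher ones with only the groups compared (67 higher, 93 lower) and without CKO_6h 11.18 (51 and 62). They also did with labelled males (49 and 58), a setting that keeps CKO_0h 4.24 and CKO_0h 5.6 despite their Xist. With a mean CPM of at least 1, the Ddx3y level and CTL_6h 4.24 left out there were 380 higher and 386 lower. That setting, chosen after seeing the data, called the most genes, 766. The count ranged from 49 without CTL_0h 4.29 to 283 without CTL_6h 4.24.

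After 6 h of stimulation Syn3, Ptgir and Myo6 again had the largest rises in CKO among the annotated genes that the naming rule admits, and Foxp3 and Gpr83, genes of regulatory T cells, were higher too. Syn3 was 6.73-fold higher in CKO (log2 2.75 ± 0.23, adjusted p = 1.3e-06), Ptgir 4.86-fold (2.28 ± 0.19, 1.11e-06), Myo6 4.14-fold (2.05 ± 0.19, 8.88e-06) and Igsf23 3.65-fold (1.87 ± 0.19, 1.53e-05), each in 3 of 3 CKO libraries. Foxp3, the transcription factor that defines regulatory T cells, was at 120 ± 23.5 CPM (SD, n = 3) in CKO and 49.1 ± 11.5 CPM (SD, n = 5) in CTL (1.29 ± 0.27, edgeR adjusted p = 0.0488). Gpr83 (1.35 ± 0.26, adjusted p = 0.0244), Ccr6 (1.67 ± 0.34, 0.0368), Lamc1 (1.46 ± 0.24), Mrgpre (1.34 ± 0.26) and Trib3, a pseudokinase of the amino acid stress response (1.13 ± 0.19, 0.0104), were also higher. Lower in CKO were Prss12 (−1.63 ± 0.29), Zmat1 (−1.07 ± 0.13, adjusted p = 0.000299), Ggt5 (−0.91 ± 0.17), Btbd2 (−0.81 ± 0.16), Dnajc15 (−0.71 ± 0.15), the death ligand gene Fasl (−0.61 ± 0.12) and Tecpr2 (−0.57 ± 0.12).

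Altogether 82 genes were called at 6 h, 71 higher and 11 lower. With CKO and CTL libraries blocked by number, Btbd2, Dnajc15, Fasl and Tecpr2 were no longer called (adjusted p = 0.179, 0.153, 0.114 and 0.239), and 52 genes were called in all, 41 of them shared with the 82. The calls on Syn3, Ptgir, Myo6, Igsf23 and Zmat1 held in each of the 20 fits that left out a library. Without CKO_6h 5.6 the adjusted p of Foxp3 was 0.543, and its call ended in 14 of the 20 fits. Without CKO_6h 5.13 Ccr6 stood at 0.485 and Gpr83 at 0.223, with calls ended in 8 and 5 fits. Of the activation genes, edgeR did not call Nr4a1 (−0.28 ± 0.29), Tnf (−0.28 ± 0.32) or Nfkb1 (−0.03 ± 0.21). Among the 25 cytokine genes edgeR called 0, against 9 at an unadjusted p under 0.05 and 3 by DESeq2. Cd4 was at 0.78 ± 0.20 (adjusted p = 0.125) and Runx1 at 0.55 ± 0.15 (0.169).

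Lists at 6 h repeated part of the 0 h picture, while the naive and quiescence list was called in the opposite direction. Camera called 18 of the 38 (17 higher, 1 lower), and 0 with an estimated correlation. Fry called 1 list, lower in CKO, and kept 0 of the 18 calls. All 9 Th17 genes were positive (median 1.27, adjusted p = 1.48e-06; 1 called, 4 adjusted over the list alone), as were 12 of 13 on the regulatory T cell list (median 0.41, adjusted p = 1.64e-06; 2 called, 4 adjusted over the list alone). For both lists the adjusted p was 0.404 with an estimated correlation. Of 17 B cell markers 15 were positive (median 0.82, adjusted p = 2.14e-05; 0.404 with an estimated correlation), and of 14 myeloid markers 12 (median 0.55, adjusted p = 0.00306; 0.404 with it). On these 2 lists edgeR and DESeq2 called 0 members, against 5 and 1 at an unadjusted p under 0.05, and 0 on either list adjusted over the list alone. Parts of the antigen receptor signalling machinery were positive in 27 of 33 members (median 0.12, adjusted p = 1.99e-05) and naive and quiescence genes in 23 of 24 (median 0.20, adjusted p = 2.14e-05), each at an adjusted p of 0.404 with an estimated correlation, with 0 called by edgeR on either list, 2 and 1 by DESeq2, 6 and 4 at an unadjusted p under 0.05, and 2 and 0 adjusted over the list alone. The median log2 fold of all genes tested was −0.29 at 6 h and −0.04 among those with a mean CPM of at least 1, a filter chosen after seeing the data. Under it the camera calls were Th17 (adjusted p = 0.00947), regulatory T cell (0.00405) and B cell (0.00947) higher, and ribosome biogenesis (0.00111), early activation transcription factors (0.0279) and cytokines (0.0384) lower, each at an adjusted p of 0.919 with an estimated correlation. The calls on myeloid markers (adjusted p = 0.242), receptor signalling parts (0.146) and naive and quiescence genes (0.146) ended under it. Under that filter 118 genes were called, 70.3% of them higher, against 86.6% without it. DESeq2 called 432 genes, 75.5% of them higher. A fit with the 6 h libraries alone called 8. Leaving out single libraries gave 16 without CKO_6h 5.6 to 212 without CTL_6h 5.13.

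The genotype calls at both times overlapped. A total of 26 genes were higher in CKO at 0 h and at 6 h, where independent lists of these lengths give 0.164 (one-sided Fisher exact p = 1.49e-52), and 8 were lower at both, against 0.0212 (p = 1.78e-20). The shared higher genes include Syn3, Myo6, Ptgir, Igsf23, Lamc1, Gpr83 and Ccr6, and the shared lower ones Pcbp2, Prss12, Ggt5, Btbd2, Tecpr2 and Zmat1. Among the 119 genes called at 0 h, 113 had the same sign at 6 h, and across them the fold changes correlated at r = 0.893. Across the 14446 genes with a mean CPM of at least 1 the correlation was 0.0852. These correlations are across genes, which are not independent replicates. No library was contrasted in both comparisons, but both came from 1 fit that shared each gene's spread and the sex term. The Fisher p is therefore only a reference against independent lists. Libraries at both times also carry the same numbers, so the animals may be shared.

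After 6 h with beads, CTL cells had higher levels of genes of the T cell activation program. No library of cells cultured for 6 h without beads was analysed here, so the stimulus and the culture cannot be separated in any comparison of 6 h with 0 h. Il2, the T cell growth factor gene, rose from 1.89 ± 0.485 CPM (SD, n = 6) to 106 ± 56.5 CPM (SD, n = 5), a log2 change of 5.82 ± 0.41 (edgeR adjusted p = 2.1e-09), and the interferon-inducible GTPase gene Gbp2 from 87.0 ± 19.5 to 2438 ± 501 CPM (4.80 ± 0.20). Of 27 early activation transcription factors and their companions 20 rose and 1, Batf3, fell. Nr4a3 (4.22 ± 0.22), Irf4 (4.12 ± 0.31) and Fosl2 (3.46 ± 0.20) were among them. Cytokine and chemokine genes rose in 20 of 25 cases, including Il13 (5.73 ± 0.50), Lif (4.44 ± 0.34) and Tnf (2.84 ± 0.27), while Osm, Ccl5 and Ltb fell. Dtx1, which encodes a Notch pathway ubiquitin ligase, fell by 5.43 ± 0.20 on the log2 scale, from 497 ± 94.7 to 11.8 ± 2.76 CPM.

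The remaining largest rises were Tnnt2 (5.99 ± 0.36), which encodes cardiac troponin T, Lad1 (5.14 ± 0.33), the stress-induced factor Atf3 (5.02 ± 0.47), Cdkn1a (4.52 ± 0.26) and Gbp11 (4.46 ± 0.21). Feedback genes of NF-kB rose in 10 of 15 cases with Tnfaip3 at 2.14 ± 0.19, activation receptors in 12 of 19 with 2 lower (Il2ra 3.43 ± 0.38, Tnfrsf9 2.56 ± 0.23), and ribosome biogenesis genes in 17 of 25 (Nop16 1.43 ± 0.18, Ncl 1.04 ± 0.17). In the same libraries 25 of 33 antigen receptor signalling parts fell and 1, Bcl10, rose. The kinase gene Lck fell by 1.59 ± 0.11, Lat by 1.5 ± 0.10 and Themis by 1.69 ± 0.13 on the log2 scale. Memory and effector genes fell in 19 of 30 cases and rose in 1 (Vim −2.29 ± 0.19, S100a4 −2.52 ± 0.27). Counts adjusted over the list alone were the same for these lists except for 26 receptor signalling parts lower. Camera adjusted p was 2.43e-07 for the transcription factors, 0.000937 for cytokines, 0.0087 for NF-kB feedback, 0.0194 for ribosome biogenesis, 8.51e-13 for receptor signalling parts and 5.76e-07 for memory and effector genes, and 0.0849 for activation receptors, which was not called. With an estimated correlation these were 0.446, 0.536, 0.656, 0.689, 0.446 and 0.446, and 0.687 for activation receptors. With the number as a block the ribosome biogenesis list was no longer called (adjusted p = 0.113).

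Markers of cells outside the sorted population fell at 6 h as well. B cell markers fell in 16 of 17 cases (Ighm −2.64 ± 0.20, Cd22 −3.17 ± 0.40; adjusted p = 3.53e-06, and 0.446 with an estimated correlation), myeloid markers in 10 of 14 (Lyz2 −4.33 ± 0.59; 0.000153, and 0.446) and natural killer and γδ T cell markers in 6 of 9 (Klrb1c −2.38 ± 0.30; 0.00815, and 0.562); the counts adjusted over the list alone were equal. The largest falls included Itgax (−4.56 ± 0.64), which encodes CD11c and is on the dendritic cell list. Others were Mmp9 (−4.64 ± 0.54), Tgfbi (−4.49 ± 0.53), Slc16a5 (−4.99 ± 0.19), Cyp27a1 (−4.40 ± 0.58) and Zfp683 (−4.13 ± 0.32). The cell type in which these genes fell was not tested. Of 7 stromal and endothelial markers 5 rose and 1 fell, by either adjustment, with Dcn at 4.43 ± 0.83 and Col1a2 at 3.44 ± 0.51, and of 3 platelet markers 2 rose (3 adjusted over the list alone), with Pf4 at 3.66 ± 0.78. Camera did not call these lists (adjusted p = 0.273 and 0.265).

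In CTL 17791 of 28082 genes were called, 11684 higher and 6107 lower at 6 h, and 54.2% of these calls had a mean CPM under 1. Olfactory and vomeronasal receptor genes, which T cells are not known to use, moved with them. Of 451 tested, 404 were called higher and 6 lower. As a share of the library total they took a median of 55.3 CPM in CTL at 0 h (43.4 to 193), 64.3 in CKO at 0 h (40.9 to 107), 216 in CTL at 6 h (131 to 2282) and 157 in CKO at 6 h (141 to 183), and library 4.24 held the highest value in CTL at both times. Among genes with a mean CPM of at least 1, a filter chosen after seeing the data, 7653 genes were called, 52.5% of them higher, against 65.7% over all genes, and the median log2 fold of all genes was 0.03 in place of 0.31. Without CTL_6h 4.24 the count was 15561 over all genes.

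**Figure D2:**
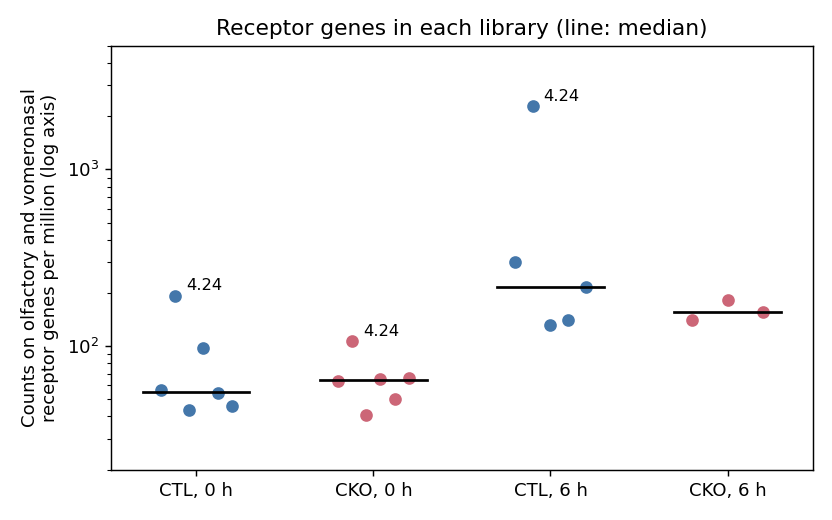
Summed counts of olfactory and vomeronasal receptor genes as CPM of each library's total, on a log axis, by group; points are libraries and bars the group median. The 6 h CTL library 4.24 stands at 2282 CPM, and the other 7 libraries at 6 h lie between 131 and 298.

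CKO cells after 6 h with beads showed many of the same changes. Il2 rose from 1.72 ± 0.291 CPM (SD, n = 6) to 95.3 ± 77.2 CPM (SD, n = 3), a log2 change of 5.75 ± 0.42 (edgeR adjusted p = 1.16e-08). Early activation transcription factors rose in 20 of 27 cases, with Fosl2 at 4.20 ± 0.22, Nr4a3 at 4.05 ± 0.23 and Nr4a2 at 3.77 ± 0.34. Cytokine genes rose in 19 of 25, with Il17f at 5.00 ± 0.55, Il22 at 5.58 ± 1.10 and Lif at 3.96 ± 0.36. Il17f went from 0.206 ± 0.0857 to 6.79 ± 6.00 CPM (SD) and Il22 from 0.0786 ± 0.0812 to 3.87 ± 4.39 CPM (SD), both from low levels. The receptor signalling parts fell in 20 of 33 cases and rose in 2 (Lat −1.33 ± 0.12, Lck −1.40 ± 0.14), and memory and effector genes fell in 19 of 30 and rose in 1. Other leading rises were Tnnt2 (5.87 ± 0.38), Gbp2 (5.07 ± 0.21), Lad1 (4.90 ± 0.35) and Atf3 (4.77 ± 0.49), and the leading falls Tgfbi (−6.00 ± 0.74), Cyp27a1 (−5.77 ± 0.79), Slc16a5 (−5.21 ± 0.25), Dtx1 (−4.98 ± 0.24), Ffar2 (−4.86 ± 0.91), Spns3 (−4.71 ± 0.75), Itgax (−4.67 ± 0.82) and Ampd1 (−4.56 ± 0.42).

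The NF-kB feedback list rose in 11 of 15 members in CKO (Tnfaip3 2.09 ± 0.21), activation receptors in 7 of 19 with 2 lower (Il2ra 3.05 ± 0.40), and ribosome biogenesis in 10 of 25 (Ncl 0.99 ± 0.20). Adjusted over the list alone these were 11, 8 and 12 higher, the transcription factors 21, the cytokines 19, and the receptor signalling parts 24 lower and 3 higher. Camera adjusted p was 3.42e-11 for the transcription factors, 3.11e-06 for cytokines, 2.81e-07 for NF-kB feedback, 7.64e-12 for receptor signalling parts and 1.75e-08 for memory and effector genes, each 0.241 with an estimated correlation. Ribosome biogenesis (0.00446) and activation receptors (0.0427) stood at 0.611 with it. Camera called 7 lists higher in CKO. It called 4 higher with the number as a block, and 4 without the sex term or without CTL_6h 4.24. Here too B cell markers fell in 13 of 17 cases (3.17e-07, and 0.244 with an estimated correlation), myeloid markers in 10 of 14 (6.52e-07, and 0.241) and natural killer and γδ T cell markers in 7 of 9 (0.000128, and 0.241), while 169 of the 451 receptor genes tested were called higher and 5 lower. Pcbp2, already low in CKO, fell by a further 0.96 ± 0.19 on the log2 scale (adjusted p = 0.00113). In CKO 9203 genes were called, 5514 higher and 3689 lower. With a mean CPM of at least 1 there were 4956, of which 47.6% were higher against 59.9%, and against a fold of 1.5 there were 4916. Leaving out CKO_6h 11.18 gave 4848 calls, leaving out CKO_6h 5.13 gave 5983, and leaving out CTL_6h 4.24 gave 12042.

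**Figure D3:**
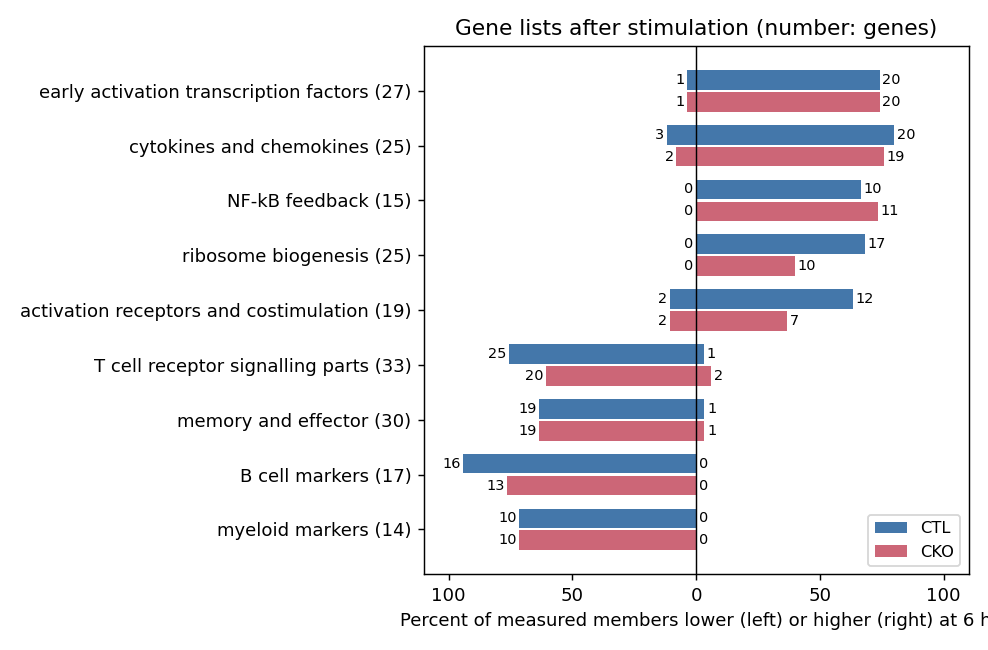
Percent of the measured members of gene lists called higher (right) or lower (left) at 6 h than at 0 h, in CTL and in CKO; the number at each bar is the count of genes. Early activation transcription factors were called higher in 20 of 27 members in both genotypes, and B cell markers lower in 16 of 17 members in CTL and 13 of 17 in CKO.

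Between the genotypes the response to stimulation was broadly shared. Calls in both genotypes numbered 5195 higher, where independent lists give 2290, and 3093 lower, against 802. Of the calls, 54.2% in CTL and 47.9% in CKO had a mean CPM under 1, where background counts may hold part of the rises. Both responses came from the same fit and some numbers recur in both genotypes, so independent lists are only a reference. Of the 8292 genes called in both, 8288 had the same sign. Across the 14446 genes with a mean CPM of at least 1 the fold changes correlated at r = 0.854, across genes, and 11244 had the same sign. The interaction test asks whether the response itself differs. For it edgeR called 0 of 28082 genes (2725 at an unadjusted p under 0.05, smallest adjusted p 0.465), and DESeq2 called 0 (3277, smallest adjusted p 0.0546). The response of Tnf differed by −0.15 ± 0.40 on the log2 scale, that of Nr4a1 by −0.35 ± 0.38, Tcf7 by 0.50 ± 0.25 and Pcbp2 by −0.91 ± 0.24. Il2 and Cdkn1a were chosen here after their values were seen. Their responses differed by −0.07 ± 0.54 and −1.70 ± 0.38, and neither was called (adjusted p = 0.948 and 0.465). In the simulated counts, drawn without pairing or background reads, this test recovered 29.9% of genes whose response differed 2-fold. Many differences of that size would thus not be detectable here.

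**Figure D4:**
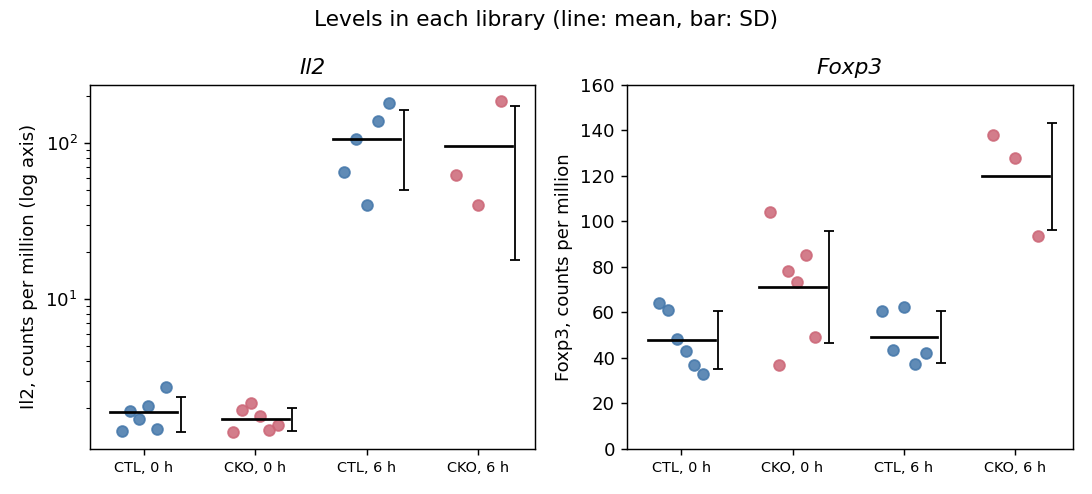
Il2 and Foxp3 in every library, in CPM, by genotype and time; points are libraries and bars the group mean with its SD, with the Il2 axis on a log scale. Il2 rose to 106 CPM in CTL and 95.3 CPM in CKO, while Foxp3 at 6 h was 49.1 CPM in CTL and 120 CPM in CKO.

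Camera called 4 of the 38 lists for the interaction, each with a less negative or more positive response in CKO: naive and quiescence genes (median log2 difference 0.27, adjusted p = 1.21e-06), receptor signalling parts (0.16, 5.81e-05), splicing regulators (0.15, 0.00261) and NF-kB feedback (0.17, 0.0476). Over all genes tested the median log2 difference was −0.27, so these lists stand above a downward shift. Fry called 0 lists. With an estimated correlation the adjusted p of the 4 lists was 0.965 for each, and camera called 0 lists among genes with a mean CPM of at least 1. With the Ddx3y level under that filter it called 3 lists (1 higher, 2 lower), and with library CTL_6h 4.24 left out too it called 8 (2 higher, 6 lower), with naive and quiescence genes the one list shared with the 4. With no filter beyond a single count it called 14, each higher and the 4 among them. With the number as a block it called 6 (4 higher, 2 lower), and NF-kB feedback was no longer called (adjusted p = 0.132). Without the sex term it called 4 (3 higher, 1 lower), and neither NF-kB feedback (0.503) nor splicing regulators (0.0634) was among them. Leaving out CTL_6h 4.24 alone gave 7 lists (2 higher, 5 lower; 2 of them among the 4), leaving out CKO_6h 5.13 gave 12, leaving out CTL_6h 10.28 gave 8, and leaving out CTL_0h 9.20 gave 7. The other single libraries gave 3 to 6, and without CKO_6h 11.18 the call stood for 2 of the 4. On the 4 lists called by the test as written beforehand, edgeR called 0 members, over all genes and adjusted over the list alone, and DESeq2 called 0, against 4, 2, 2 and 1 at an unadjusted p under 0.05.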

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

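The tests of library depth, of receptor genes being turned on, of background reads in low genes, of regulatory-type cells and of both loci were chosen only after the result was seen; the tests of exon length, of sex labels and of other splits were written before it.

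Counts on olfactory and vomeronasal receptor genes stood apart in library 4.24 of CTL, at 193 CPM of the total at 0 h (others 43.4 to 97.0) and 2280 at 6 h (others 131 to 298), and the 6 h library also had the lowest total in its group, 26.4 M counts (others 62.4 to 69.4). Genomic DNA or other unspliced background reads are a candidate source, but the tests made for them cannot decide. Counts in this library followed exon length over 1702 receptor genes (Spearman correlation 0.417 across genes, permutation p = 1e-04, the smallest that 10000 permutations can give). Counts of true transcripts also rise with exon length, so this favors neither source. Among calls with a mean CPM of at least 1 in CTL the share of higher calls was 52.5%, against 65.7% over all genes. TMM scaling centers the fold changes of abundant genes, which draws that share toward evenness whatever the source. Library depth cannot be told apart, because the 6 h libraries inside the 0 h range of totals held 139.7 and 183.2 CPM, above the 0 h median of 59.8 but inside the 0 h range of 40.9 to 193, and library 4.24 at 6 h lies outside that range of totals. Stimulation turning these genes on cannot be told apart either for the remaining 6 h libraries, because 1 library at 0 h was as high as the lowest at 6 h. Background counts may hold part of the calls on low genes at 6 h.

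The regulatory T cell list lay higher in CKO at both times, in cells sorted as CD25-. The most abundant members were Izumo1r, at 206 ± 44.5 CPM in CTL and 324 ± 99.1 CPM in CKO at 0 h, and Ikzf2, at 138 ± 31.7 and 271 ± 116 CPM (SD, n = 6 each); 5 of the 13 members are also on the activation or anergy lists. The test of sex labels used 6 h, where the median log2 fold was 0.44 with the Ddx3y level and 0.41 with the labels. Each 6 h label matched Xist, so this test could hardly decide. At 0 h, outside that test, both disagreeing labels lie in CKO. There the median was 0.58 with the Ddx3y level and 0.53 with the labels. This argues against wrong labels as the source of the higher list, not against the labels being wrong. More cells of a regulatory type inside the gate and a change of expression within the same cells cannot be told apart. At least 90.9% of the members without a call had a positive fold at either time, but 12 of 13 members were already seen to be positive, so this share favors neither.

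At the Pcbp2 locus, 3 of 57 other tested genes within 1 Mb were called at 0 h, against 115 of 28024 elsewhere (one-sided Fisher exact p = 0.00179). These genes, Gm26518, Gm27406 and Map3k12, were chosen after their values were seen and all overlap Pcbp2, so this p restates what was seen, and edgeR called 0 of the 54 that do not overlap it. Gm26518 (log2 −2.63) and Gm27406 (−2.98) were lower in CKO, and Map3k12 was higher (1.04 ± 0.11). Reads shared with Pcbp2 would fall with it, so the rise argues against them for Map3k12. For Gm27406, which lies inside Pcbp2 on the same strand, shared reads stay open whatever the strand setting. For Gm26518, on the opposite strand, they stay open because that setting is unknown. Changed DNA at the locus stays open for each of these genes. Gm33707, a processed pseudogene on chromosome 3 (GRCm38, 60769887 to 60770455), also chosen after its values were seen, stood at 52.1 ± 14.7 CPM in CKO and 0.140 ± 0.0809 CPM in CTL at 0 h (SD, n = 6 each; log2 9.06 ± 0.37), and the neighboring Gm38326 was higher as well (5.87). A linked strain segment stays open, since edgeR called 0 of the 94 other genes tested within 5 Mb where the overall rate gives 0.398, and an inserted transgene was not tested.

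Other splits of the libraries bear on whether chance can be excluded. For genotype at 0 h, 1 of 100 splits, the real one, called as many as 119 genes (highest other 21). Among the 32 splits that part every number the highest other called 0. Chance is an unlikely source, but the real split is among those counted, so these shares cannot exclude it. At 6 h, 5 of 56 splits called at least 82 genes and the highest other called 5435, so chance cannot be excluded; that split set CTL libraries 4.29, 4.24 and 9.20 apart, which points to a structure among the 6 h libraries. For stimulation, 1 of 100 splits in CTL called as many as 17791 genes (highest other 15144) and 1 of 84 in CKO as many as 9203 (highest other 3352), so chance can be excluded for both. For the interaction 0 genes were called, a count that each of the 100 splits reaches by definition, so the splits say nothing on chance there; the highest other called 4295, which points to a structure among the libraries.

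Single libraries also lay far from the rest of their group in 9 levels of genes named in the genotype comparisons. Of 123 groups of values screened, 12 held such a library, receptor signal and totals included, where chance gives about 6.2. In CTL at 0 h these were Epb41l5 at 3.22 CPM in 4.24 (others 2.00 to 2.28), Zmat1 at 21.2 CPM in 5.6 (16.4 to 18.1) and Nr4a1 at 149 CPM in 10.28 (59.2 to 87.0). In CKO at 0 h they were Pcbp1 at 333 CPM in 5.13 (221 to 249) and Btbd2 at 30.5 CPM in 9.20 (22.7 to 23.3). In CTL at 6 h all were in library 4.24: Pcbp2 at 262 CPM (330 to 348), Syn3 at 5.67 CPM (1.91 to 2.72), Epb41l5 at 17.4 CPM (3.50 to 5.45) and Ptprc at 969 CPM (2060 to 2280).

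The response to stimulation differed between genotypes by camera for naive and quiescence genes (adjusted p = 1.21e-06), receptor signalling parts (5.81e-05), splicing regulators (0.00261) and NF-kB feedback (0.0476), each at an adjusted p of 0.965 with an estimated correlation. NF-kB feedback was no longer called with the number as a block (adjusted p = 0.132), and neither it (0.503) nor splicing regulators (0.0634) without the sex term. With a mean CPM of at least 1 none of them was called with the sex label, and naive and quiescence genes were with the Ddx3y level (adjusted p = 0.0156). Without CTL_6h 4.24 the direction turned for splicing regulators (median −0.03), and with that filter and the Ddx3y level as well for NF-kB feedback (−0.10).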

How the results depend on the processing

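The filter on mean CPM, the use of Ddx3y or Xist for sex, and the exclusion of the 6 h CTL library 4.24 or of a pair of 0 h CKO libraries were chosen after seeing the data, the remaining settings before. For genotype at 0 h, 119 genes became 421 with DESeq2, 198 without sex and 290 with the number as a block beside the sex label. They became 210 with 1 surrogate variable, 14 against a fold of 1.5, 224 with the Ddx3y level and 223 with sex from Xist. Restricted to a mean CPM of at least 1 they became 293 with Ddx3y and 295 with Xist, 766 with Ddx3y and library 4.24 left out, and 491 with the block as well. Without single libraries the count ran from 49 (CTL_0h 4.29) to 283 (CTL_6h 4.24), with 52 without CTL_0h 5.13, 60 without CKO_0h 9.20, 65 without CKO_0h 4.29, 71 without CKO_0h 11.18, 74 without CTL_0h 5.6 and 79 without CKO_0h 5.6. For genotype at 6 h, 82 genes became 432 with DESeq2, 52 with the block, 8 with only the groups compared, 24 with labelled males, 53 with 1 surrogate variable and 9 against a fold of 1.5. With a mean CPM of at least 1 they became 137 with Xist, 139 with Ddx3y and 230 with library 4.24 left out too (66.5% higher, against 86.6%). Without single libraries there were 16 (CKO_6h 5.6) to 212 (CTL_6h 5.13), with 19 without CKO_6h 5.13, 38 without CTL_6h 4.29, 46 without CTL_6h 9.20, 51 without CTL_6h 10.28 and 182 without CKO_6h 11.18. For stimulation in CTL, a mean CPM of at least 1 gave 7653, 7691 with Ddx3y, 7703 with Xist, 7552 with library 4.24 left out as well as Ddx3y, and 7536 with the block added; fewer genes were tested there. Leaving out single libraries gave 15561 to 19210. In CKO a fold of 1.5 gave 4916, a mean CPM of at least 1 gave 4956, 5175 with Ddx3y, 5225 with Xist and 5899 with Ddx3y, library 4.24 left out and the block, and single libraries 4848 to 12042 (5983 without CKO_6h 5.13). The interaction stayed at 0 in each edgeR and DESeq2 setting run. Pcbp2 at 0 h stayed at 4.89% of CTL under the block, where the exact sign-flip test on 5 pairs cannot go below p = 0.0625. Leaving out single libraries gave 4.78% to 5.35% at 0 h and 2.31% to 2.94% at 6 h. The cause of the other changes was not tested.

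Of 255 values of named genes, 209 were called in the main fit. None turned direction where the main fit or the setting called the gene. Changes of sign where neither did were not counted. The block kept the call or its absence for 250, ended 4 and added 1, DESeq2 kept 253, and RLE factors kept 254. Over fits without a single library 4929 of 5100 were kept. Of 70 list calls, none was kept with an estimated correlation, 26 with fry, 60 with the block and 37 with a mean CPM of at least 1. Fry kept 13 for stimulation in CTL, 12 in CKO and 1 for genotype at 0 h. It kept 0 for genotype at 6 h and for the interaction. Camera's direction turned for these lists, given by median log2 fold. In CTL stimulation, naive and quiescence genes stood at −0.10 with a mean CPM of at least 1 (also with an estimated correlation), −0.09 with Ddx3y added and 0.08 with library 4.24 left out too. DNA replication stood at 0.02, 0.02 and 0.04, and 0.02 with an estimated correlation, and splicing regulators at −0.01 with Ddx3y and 0.11 with library 4.24 left out too. With Ddx3y, a mean CPM of at least 1 and library 4.24 left out, splicing regulators stood at −0.06 at 6 h and −0.07 in the interaction, and NF-kB feedback at −0.10 in the interaction. Without single libraries, splicing regulators in the interaction ran from −0.03 (CTL_6h 4.24) to 0.26. Ribosome biogenesis at 6 h ran from −0.54 to 0.01 (CKO_6h 5.13), and its direction by camera also turned without CTL_6h 10.28, where it stood at −0.08. The overlap of genotype calls ranged from 20 to 91 genes higher and 5 to 57 lower. No interval was drawn from depth, which was lowest in CTL_6h 4.24.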

Other observations

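Stimulation also moved genes of metabolism, interferon and the cell cycle, in the same edgeR test and on lists fixed beforehand. As 17791 of 28082 genes were called in CTL and 9203 in CKO, the number of called members alone does not set a list apart. Of 19 amino acid and one-carbon genes 10 rose and 2 fell in CTL, with Asns, the asparagine synthetase gene, at 2.17 ± 0.34 and Shmt1 at 1.81 ± 0.26, and 9 rose in CKO (10 rose and 1 fell adjusted over the list alone). Camera called this list in CKO (adjusted p = 0.0307, and 0.572 with an estimated correlation) and not in CTL (0.19). Interferon-stimulated genes went both ways: of 38, 15 rose and 14 fell in CTL, and 13 rose and 11 fell in CKO. In CTL the GTPase genes Igtp (2.28 ± 0.12) and Irgm1 (1.96 ± 0.12) rose while the antiviral gene Mx1 fell by 3.45 ± 0.20 on the log2 scale. Iron genes in CTL rose in 4 and fell in 6 of 15 cases; the transferrin receptor gene Tfrc rose (1.81 ± 0.33) and the iron exporter gene Slc40a1 fell by 4.38 ± 0.74. For glucose, the hexokinase gene Hk2 rose (2.39 ± 0.31) and the glucose transporter gene Slc2a3 fell by 1.62 ± 0.11. Heat shock genes rose in 8 of 12 cases in CTL and 3 of 12 in CKO, with Hsp90aa1 at 1.11 ± 0.22 in CTL; adjusted over the list alone it was 8 and 2. For the remaining lists of this paragraph the counts adjusted over the list alone were equal in CTL, except glycolysis with 3 higher in place of 5, and the interferon list in CKO had 14 lower in place of 11.

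Among regulators of entry into the cell cycle more genes fell than rose at 6 h: of 20, 10 fell and 3 rose in CTL (E2f2 −2.25 ± 0.18, Ccne1 −1.67 ± 0.15, Cdk2 −1.09 ± 0.11), and 9 fell and 2 rose in CKO. Adjusted over the list alone, 10 fell and 4 rose in CTL, and 10 fell and 2 rose in CKO. Camera gave adjusted p = 0.00815 in CTL and 0.00122 in CKO, and 0.446 and 0.241 with an estimated correlation. T follicular helper genes fell in 6 of 11 cases in both genotypes, among them in CTL the chemokine receptor gene Cxcr5 (−2.13 ± 0.26), Maf (−1.72 ± 0.28) and Tox2 (−2.26 ± 0.32); their adjusted p was 0.0261 and 0.0148, and 0.684 and 0.572 with an estimated correlation. In CTL the Th2 cytokine genes Il4 (3.45 ± 0.35) and Il5 (4.64 ± 0.61) and the Th17 cytokine gene Il17a (6.75 ± 1.01) rose. The level of Il17a went from 0.017 ± 0.0285 to 1.95 ± 2.41 CPM (SD), so its fold starts near the floor. Of the p53 targets 9 rose and 2 fell in CTL, with Plk2 at 2.90 ± 0.33 and Phlda3 at 2.60 ± 0.34, and 7 rose in CKO, against 8 and 7 rises adjusted over the list alone. Camera called the p53 list in CKO (adjusted p = 0.0322, and 0.38 with an estimated correlation) and not in CTL (0.19). Fewer lists were called higher in CKO with the number as a block (4 against 7). The calls on the p53 and amino acid lists may therefore not stand. Pcbp4 fell by 0.62 ± 0.13 in CTL (adjusted p = 0.000435), and Runx1 by 0.89 ± 0.13.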
